A study of Mus musculus with 9 samples.

How the data were processed

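The series profiled RNA from the colon of male C57BL/6J mice, an inbred laboratory strain. Per the labels' protocols, all mice ate a high-fat control diet with 40% of its energy from fat during a run-in, and then either stayed on it or received the same diet with 0.2 µmol heme per g, heme being the iron-containing pigment of red meat. Mice were killed at different days, colons were opened and washed, and the epithelial cells were scraped off. RNA was isolated from each animal and then pooled within a diet and day, and each pool was hybridised to 1 Affymetrix whole-transcript mouse array. The table holds 9 arrays, of which 5 are control pools (days 0, 2, 4, 7 and 14) and 4 are heme pools (days 2, 4, 7 and 14). Every pool held RNA of 4 mice except the control pool of day 2, which held 3. Day 0 is the end of the run-in and has no heme pool.

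The values analysed are the deposited log2 expression values per probeset, made by the authors with RMA (robust multi-array averaging) per the submitters' processing notes, whose version is not given in the sources used here. RMA corrects background, quantile-normalizes the arrays together and summarises the probes of a probeset by median polish on the log2 scale. The array medians lay between 5.895 and 5.963 log2 and the upper quartiles between 7.673 and 7.794. Median polish leaves identical values in several arrays: 5179 of the genes tested had the same value in 2 or more control pools, and 23 had it in all 5, so the spread of such genes is understated. An array has no read depth, and the number of arrays limits the precision.

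Probesets were named through the platform annotation supplied with the table. Of 35556 probesets, 21789 had 1 gene symbol, 1621 had several and 12146 were unnamed here. Of the named probesets, 21698 were matched by Entrez ID to the RefSeq gene table, which changed 0 symbols. Probesets with several genes were left out. Of the 19938 genes, 999 had more than 1 probeset, and the probeset with the highest mean was kept. Genes whose mean over the arrays lay at or above the 25th percentile of gene means (4.716 log2) were tested, 14953 in all.

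Tests were run with limma 3.58.1 in R 4.3.3. Tables were prepared with Python 3.11.15 and figures drawn with matplotlib 3.10.9. Linear models were fitted to log2 values with lmFit and moderated with eBayes with an intensity trend. P-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The diet comparison set the 4 heme pools against the 5 control pools. Each heme day was also compared with the 5 control pools. A heme day has only 1 pool, so the spread in these tests comes from the control pools (4 residual degrees of freedom) and the lone heme pool is assumed to vary like them. The late-minus-early comparison tested whether the difference between diets on days 7 and 14 differed from that on days 2 and 4, over the 8 arrays of those days. A slope on log2(day + 1) over the 5 control pools asked whether the control diet alone moved with time. No diet and day has a replicate pool. All p-values therefore measure the spread between pools of different days, not between animals. The labels give the control and heme pools of days 2, 4, 7 and 14 a shared day on diet, though not shared animals, and the deviations of the 2 pools correlated with r = 0.658, 0, 0.3 and 0.204 on those days. Pools of different days correlated by up to 0.396, and of the same-day values only that of day 2 lay above this. As the labels share the day, the fit with the day as a block is given beside a result where it changes the call. Its calls had been seen when this was decided.

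There were 41 gene lists, of pathways, colon cell types and cells or organs that a colon scraping could also hold, written from textbook knowledge. Of their 613 genes, 564 were matched, and 40 lists had at least 4 genes tested. The exception was a list of erythrocyte genes, which gives no result here. Lists were tested with camera, which asks whether the members of a list shift relative to all other genes, with a preset correlation between genes of 0.01, and adjusted over lists. With the correlation estimated from these arrays no list was called in any comparison, and that p is given beside each list described. For the diet comparison the mean of each list was also compared by an exact permutation of the 9 arrays, counting differences in either direction, over 126 splits, with a smallest possible p of 0.00794. An exact permutation within days was added after the results were seen. Counts of called members are given over all genes tested and adjusted over the list alone.

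Named genes follow a fixed rule. For the diet comparison these are the 12 highest and 12 lowest log2 fold changes among called genes that lay on the same side of the same day's control pool on all 4 days. The day and late-minus-early comparisons name the 6 highest and 6 lowest called genes, and the control slope the 3 highest and 3 lowest. From each list described come the 4 members with the smallest p, called or not. A set of 25 genes known from earlier work on heme and the colon is always eligible, of which 21 were matched. It holds all 4 genes of the growth inhibitor list. Predicted and numbered transcripts, olfactory receptors and unnamed probesets were skipped. Other names are said to be chosen after their values were seen.

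The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except the alternatives and tests said to have been chosen later. Alternatives were eBayes without the trend or with robust moderation, no filter or a 50th percentile filter, a further quantile normalization, the mean of a gene's probesets, an estimated correlation for camera, the day as a block, the 8 arrays of matched days, a 1.5-fold minimum, the same day's control pool alone, the heme pools alone, and each pool left out in turn. The main gene comparisons, and camera for the diets, were tested on simulated data with the real genes. The block fits, permutations and other camera tests were not. Simulated heme pools had the spread of the control pools, with genes drawn independently. The heme array of day 14 spread more widely, so its share may not hold. With 100 genes raised or lowered by 0.5 on the log2 scale and 100 by 1, the diet comparison recovered 86% and 100% of them. False calls numbered 2 to 9 per comparison. The recovered shares were 62% and 94% for day 2, 64% and 92% for day 4, 47% and 90% for day 7, 69% and 90% for day 14, 33% and 71% for late minus early, and 96% and 99% for the control slope. Camera called 0 lists in simulated data without a change, but a median of 10 in other splits of the real arrays, against 14 in the real one.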

Results

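Gene expression was measured in scrapings of the colon epithelium of mice that ate a diet rich in fat, with or without added heme. Per the series title, the study asked which responses to dietary heme begin at once and which follow with a delay. There were 5 control pools, of days 0, 2, 4, 7 and 14, and 4 heme pools, of days 2, 4, 7 and 14, each on 1 array. All values are log2 expression, and 14953 genes were tested. By chance alone about 748 of them would fall at an unadjusted p under 0.05 in a comparison.

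The strongest difference between the diets was in genes of fatty acid handling. Fabp1, the liver-type fatty acid binding protein (probeset 10538965), stood at 8.47 ± 1.29 log2 in the heme pools (SD, n = 4) and at 4.91 ± 0.34 in the control pools (SD, n = 5), an 11.8-fold rise (log2 fold change 3.56, SE 0.49, adjusted p = 0.0113). Pdk4, the kinase that shuts off pyruvate dehydrogenase (probeset 10543017), rose 3.69-fold, from 7.92 ± 0.36 (SD, n = 5) to 9.80 ± 0.33 (SD, n = 4) (adjusted p = 0.006). Cyp4a10, a fatty acid hydroxylase, rose 4.11-fold (adjusted p = 0.0165), Acaa1b, a peroxisomal thiolase, 2.96-fold (adjusted p = 0.0064), and Slc27a2, which takes up and activates long fatty acids, 2.73-fold (adjusted p = 0.006). The control level of Fabp1 lay close to the filter value of 4.716 log2, and that of Cyp4a10 (4.24) below it, so their folds here and by day rest on a dim control signal. Creb3l3, a transcription factor of lipid metabolism, Acot2, a mitochondrial acyl-CoA thioesterase, and Vnn1, a pantetheinase, rose by 1.35, 1.31 and 1.26 on the log2 scale (adjusted p = 0.006, 0.0087 and 0.006). Of the 25 measured genes on the list of fatty acid oxidation and PPAR alpha targets, 21 rose over all genes tested and 24 adjusted over the list alone, and none fell. The list mean was 0.91 log2 higher in the heme pools (camera adjusted p = 1.68e-38, adjusted p = 0.281 with an estimated correlation). Smaller rises on this list included Hadha of the mitochondrial trifunctional protein and the thiolase Acaa2, both by 0.50 log2 (adjusted p = 0.006 each). Angptl4, a secreted inhibitor of lipoprotein lipase, rose 2.04-fold (adjusted p = 0.006). Cpt1a, which admits fatty acids to mitochondria, had a log2 fold change of 0.21 and an adjusted p of 0.0521. With the day as a block Fabp1 and Cyp4a10 lost their calls (adjusted p = 0.0523 and 0.0614).

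Enzymes of antioxidant and detoxifying defence formed the other group of large rises. Akr1b8, an aldo-keto reductase that clears reactive aldehydes, rose 3.45-fold (log2 fold change 1.78, SE 0.25, adjusted p = 0.0113). Cbr3, a carbonyl reductase, rose 2.84-fold (adjusted p = 0.0234), Me1, the NADPH-yielding malic enzyme, 2.78-fold (adjusted p = 0.0165), and Akr1c18, a steroid-reducing member of the aldo-keto family, 2.56-fold (adjusted p = 0.0449). On the list of Nrf2 targets, 5 of 26 measured genes rose over all genes tested and 15 adjusted over the list alone. Among the 5 were Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis (0.62 log2, adjusted p = 0.0208), and the exporter Abcc3 (0.36 log2, adjusted p = 0.0187). The list mean was 0.42 log2 higher (camera adjusted p = 1.08e-13, adjusted p = 0.439 with an estimated correlation). Other well-known targets did not pass over all genes tested, with log2 fold changes of 0.61 for Nqo1 (adjusted p = 0.0555), 0.54 for the heme-degrading enzyme Hmox1 (adjusted p = 0.305), 0.38 for Gclm (adjusted p = 0.114), 0.32 for Srxn1 (adjusted p = 0.18) and 0.20 for Txnrd1 (adjusted p = 0.0743). Catalase (Cat) rose 1.72-fold (adjusted p = 0.006) and the superoxide dismutase Sod1 by 0.26 log2 (adjusted p = 0.0187), 2 of 14 genes on a list of other antioxidant enzymes, with 3 higher adjusted over the list alone (list mean 0.10, camera adjusted p = 0.0137, adjusted p = 0.487 with an estimated correlation). Of 12 xenobiotic metabolism genes, 3 rose, namely the retinaldehyde dehydrogenase Aldh1a1 (0.79 log2, adjusted p = 0.0133), the drug exporter Abcb1a (0.23, adjusted p = 0.0187) and Cyp2c66 (0.58, adjusted p = 0.0387). Adjusted over the list alone, 5 of the 12 were higher and 1 lower (list mean 0.13, camera adjusted p = 0.0171, adjusted p = 0.487 with an estimated correlation). The call of the other antioxidant enzymes was lost without the heme pool of day 7 (adjusted p = 0.0546) and that of xenobiotic metabolism without the heme pool of day 4 (adjusted p = 0.052). Metallothioneins and heat shock genes had a list mean of 0.22 log2, with 0 of 11 called over all genes tested and 3 adjusted over the list alone (camera adjusted p = 0.00187, adjusted p = 0.439 with an estimated correlation). Mt1 was 0.49 and Mt2 0.80 higher in that list (adjusted p = 0.055 and 0.0874). With the day as a block the calls of Akr1c18 (adjusted p = 0.0618), Gclc, Abcc3 and Abcb1a (0.0523 each) and Sod1 (0.0716) were lost.

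Cell cycle genes were higher as a group although no single member was called over all genes tested without the day as a block. With it Ndc80 and Cdc20 were called (0.55 and 0.40 log2, adjusted p = 0.0192 and 0.0381). The 25 mitosis genes had a mean log2 fold change of 0.42, and 25 of 25 were higher in the heme pools (camera adjusted p = 2.09e-17, adjusted p = 0.439 with an estimated correlation). Adjusted over the list alone, all 25 were called. Examples were Ndc80 of the kinetochore (0.50, adjusted p = 0.0711), Cdc20, an activator of the anaphase-promoting complex (0.37, adjusted p = 0.111), and its partner enzyme Ube2c (0.47, adjusted p = 0.114). The proliferation marker Mki67 had a log2 fold change of 0.40 (adjusted p = 0.169), the topoisomerase Top2a 0.39 (adjusted p = 0.135) and the replication helicase subunit Mcm5 0.19 (adjusted p = 0.372). The DNA replication list shifted by 0.13 (0 of 25 called, also 0 adjusted over the list alone, camera adjusted p = 1.99e-04, adjusted p = 0.555 with an estimated correlation), and by 0.08 without the heme pool of day 14. Subunits of the respiratory chain shifted by 0.10, with 0 of 14 called over all genes and 10 adjusted over the list alone (camera adjusted p = 4.62e-07, adjusted p = 0.439 with an estimated correlation). Genes of cholesterol synthesis shifted by 0.16, with 0 of 18 called in either way (camera adjusted p = 0.00409, adjusted p = 0.609 with an estimated correlation). Without the heme pool of day 14 that shift was 0.065 and its call was lost (adjusted p = 0.0914).

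Lower genes were fewer, and the naming rule reached 11 of them. Saa3, an acute-phase serum amyloid, was 1.88-fold lower (log2 fold change -0.91, SE 0.16, adjusted p = 0.0398), the bile acid binding protein Fabp6 1.78-fold (adjusted p = 0.039) and butyrylcholinesterase, Bche, 1.73-fold (adjusted p = 0.0183). Psmb8, a subunit of the immunoproteasome, fell by 0.54 log2 (adjusted p = 0.0165), Tgfbi, a matrix protein induced by TGF-beta, by 0.51 (adjusted p = 0.0187), and Slc5a8, which carries short-chain fatty acids and other monocarboxylates into colonocytes, by 0.46 (adjusted p = 0.0165). The smaller falls were in Slc46a3, Robo2, Akr1c14, Clic6 and Peli1, with log2 fold changes between -0.36 and -0.26. With the day as a block 8 of these 11 genes were not called, namely Saa3 (adjusted p = 0.0827), Fabp6 (0.0923), Psmb8 (0.0803), Slc46a3 (0.088), Robo2 (0.122), Akr1c14 (0.0568), Clic6 (0.088) and Peli1 (0.0923). Among lists, the clock genes were lower by a mean of -0.175 log2 (0 of 13 called over all genes, 6 lower adjusted over the list alone, camera adjusted p = 4.5e-04, adjusted p = 0.439 with an estimated correlation). In that list Dbp had a log2 fold change of -0.43 (adjusted p = 0.0874) and Per3 -0.39 (adjusted p = 0.162). Enteroendocrine genes had a mean of -0.23, with 0 of 16 called in either way (camera adjusted p = 0.0183, adjusted p = 0.439 with an estimated correlation). The hormone granule protein Chga had a log2 fold change of -0.65 (adjusted p = 0.232). A list of 4 growth inhibitors made at the epithelial surface, Ihh, Bmp2, Wif1 and Il15, had a mean of -0.33 (0 called over all genes, 3 lower adjusted over the list alone, camera adjusted p = 0.0158, adjusted p = 0.487 with an estimated correlation). All 4 also belong to the set of genes known from earlier work on heme and the colon. The calls of this list are thus not those of genes chosen without regard to heme. Interferon response genes had a mean of -0.13 (2 of 13 lower adjusted over the list alone, camera adjusted p = 0.0245, adjusted p = 0.49 with an estimated correlation) and tuft cell genes a mean of -0.18 (0 of 10 called in either way, camera adjusted p = 0.0437, adjusted p = 0.487 with an estimated correlation). Without the heme pool of day 14 the means were -0.15 for enteroendocrine, -0.22 for growth inhibitor and -0.11 for tuft cell genes, and without the control pool of day 14 it was -0.085 for interferon genes. The interferon call was lost without the control pool of day 2, the control pool of day 14 or the heme pool of day 4 (adjusted p up to 0.0954), and the tuft call without the control pools of days 2 or 4 or the heme pools of days 4 or 7 (up to 0.0727). Of 19 colonocyte genes 1 rose, the water channel Aqp8 (0.66 log2, adjusted p = 0.0113, a name chosen after its value was seen), with 4 higher and 1 lower adjusted over the list alone (list mean 0.07, camera adjusted p = 0.195, adjusted p = 0.49 with an estimated correlation). Aqp8 lost its call without the control pool of day 4 or the heme pool of day 7 (adjusted p = 0.0532 and 0.0536). The colonocyte markers Car1 and Slc26a3 and the goblet mucin Muc2 had log2 fold changes of 0.04, -0.02 and -0.08 (adjusted p = 0.452, 0.644 and 0.398).

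In all, 100 genes were called between the diets in limma, 89 higher and 11 lower in the heme pools, and 2547 had an unadjusted p under 0.05. All 100 lay on the same side of the same day's control pool on each of the 4 days. The same arrays had picked these genes, so this is not an independent check. Of the 100 genes, 15 were at least 2-fold higher. By exact permutation of the list means over the 9 arrays, the lists of fatty acid oxidation, Nrf2 targets, mitosis, respiratory chain, clock, enteroendocrine and NF-kB inflammation genes reached p = 0.00794, the smallest value possible (adjusted p = 0.0454). When pools were exchanged only within a day, which gives 16 arrangements, the smallest possible exact permutation p was 0.125, and 21 lists including these 7 reached it. The inflammation list, with a mean of -0.15, 1 of 15 genes lower over all genes and 2 adjusted over the list alone, was not called by camera (adjusted p = 0.129). Camera called 14 lists, and 22 with the day as a block. The 8 further lists had blocked means of -0.44 for smooth muscle (adjusted p = 1.95e-05), -0.28 for fibroblast (0.00112), -0.24 for MHC class II (0.0158), -0.13 for goblet (0.0197), -0.13 for macrophage (0.0292), -0.16 for endothelial (0.0319), 0.15 for wound repair (0.0351) and -0.16 for antimicrobial genes (0.041), and with an estimated correlation no list was called (smallest adjusted p 0.453). The count of called genes depended on single pools. It was 49, 58, 30, 70 and 48 without the control pools of days 0, 2, 4, 7 and 14, and 251, 97, 36 and 46 without the heme pools of days 2, 4, 7 and 14. The balance of directions moved too, with 172 higher and 79 lower without the heme pool of day 2, and 30 higher and 0 lower without the control pool of day 4. With both pools of day 7 left out, a choice made after seeing the data, it was 0 in limma (1567 at an unadjusted p under 0.05). In each of the 9 leave-one-out fits 6 of the 12 highest genes stayed called, namely Pdk4, Acaa1b, Slc27a2, Creb3l3, Acot2 and Vnn1, and 0 of the 11 lowest. Fabp1 and Akr1b8 were lost without the control pool of day 4 alone (adjusted p = 0.0532 for each). The highest adjusted p in these fits was 0.0712 for Cyp4a10 and Me1, 0.106 for Cbr3 and 0.168 for Akr1c18.

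**Figure D1:**
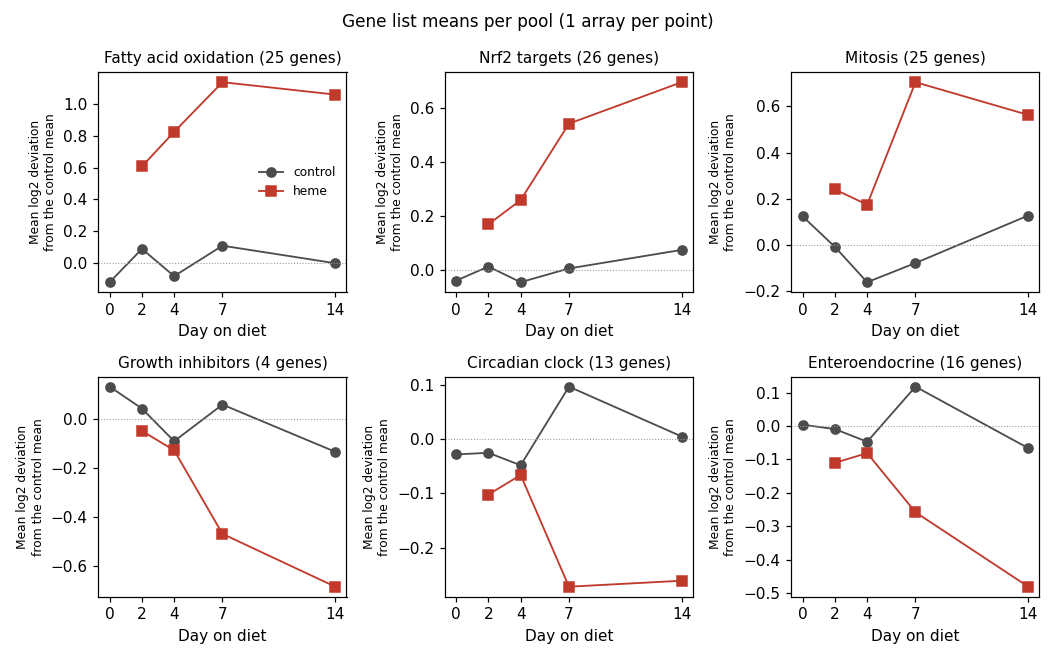
Mean log2 deviation from the mean of the 5 control pools for 6 gene lists, against the day on diet, with 1 point per pool (control in grey circles, heme in red squares). The heme pools of fatty acid oxidation genes lie between 0.61 and 1.14 on all 4 days, and those of the growth inhibitors reach -0.68 on day 14.

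After 2 days on heme no gene was called in limma, with 1385 at an unadjusted p under 0.05, but the fatty acid list was already higher. Its mean stood 0.61 log2 above the control pools, 25 of 25 members were higher, and 21 were called adjusted over the list alone (camera adjusted p = 1.55e-26, adjusted p = 0.649 with an estimated correlation). Fabp1 had a log2 fold change of 2.05, Creb3l3 1.15, Acot1 0.78 and Acot2 0.74 (adjusted p = 0.312 for each). The Nrf2 list stood at 0.17, with 5 of 26 higher adjusted over the list alone (camera adjusted p = 7.88e-05, adjusted p = 0.649 with an estimated correlation), led by Akr1b8 at 1.05 (adjusted p = 0.312), Me1 at 0.85 and Cbr3 at 0.74. Hmox1 was at 0.11 (adjusted p = 0.895). Mitosis genes stood at 0.24, with 25 of 25 higher and 0 called adjusted over the list alone (camera adjusted p = 1.82e-08, adjusted p = 0.649 with an estimated correlation). Heat shock and metallothionein genes stood at 0.23, with Hspa1a at 0.88 (camera adjusted p = 0.00977, adjusted p = 0.649 with an estimated correlation), and xenobiotic genes at 0.14 (camera adjusted p = 0.0206, adjusted p = 0.649 with an estimated correlation), a call lost without the control pools of days 2 or 4 (adjusted p up to 0.0624). The 6 lists of other cells and MHC class II that camera called lower on day 2 lay below the control mean in both pools of that day. In the heme pool the means were -0.69 for fibroblast, -0.44 for macrophage, -0.60 for MHC class II, -0.87 for smooth muscle, -0.32 for endothelial and -0.28 for B and plasma cell genes. In the control pool of the same day they were -0.58, -0.33, -0.26, -0.83, -0.28 and -0.18. Adipocyte genes lay above it in both pools (0.10 in the control and 0.07 in the heme pool), and T and NK cell and granulocyte and mast cell genes in the control pool (0.03 each). Smooth muscle was at -0.58 in the heme pool when the control pool of day 7 was left out. The highest camera adjusted p among these was 0.00812, and with an estimated correlation each had an adjusted p of 0.649 or 0.844. Genes of the exocrine pancreas were 3.19 log2 above the control mean (camera adjusted p = 4.59e-04, adjusted p = 0.649 with an estimated correlation), and in the control pool of the same day they were 2.71 above it. Without that control pool, 16 genes were called, all higher, and pancreas genes were not set apart from them.

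On day 4 the call was a single gene, Acot2, 2.22-fold higher (log2 fold change 1.15, adjusted p = 0.0483), with 1049 genes at an unadjusted p under 0.05. It was lost without any of the 5 control pools (adjusted p up to 0.347). Fatty acid genes had a mean of 0.82, with 24 of 25 higher adjusted over the list alone (camera adjusted p = 5.69e-43, adjusted p = 0.347 with an estimated correlation), and Fabp1 was at 2.93 (adjusted p = 0.151). Nrf2 targets had a mean of 0.26, with 9 of 26 higher adjusted over the list alone (camera adjusted p = 2.8e-11, adjusted p = 0.377 with an estimated correlation), and mitosis genes a mean of 0.17 (0 called adjusted over the list alone, camera adjusted p = 7.66e-06, adjusted p = 0.562 with an estimated correlation). Nqo1 was at 0.43 (adjusted p = 0.392), Hmox1 at 0.11 (adjusted p = 1) and the mitotic kinase Aurka at 0.14 (adjusted p = 0.992). NF-kB inflammation genes had a mean of -0.16 with 1 of 15 lower adjusted over the list alone (camera adjusted p = 0.00498, adjusted p = 0.377 with an estimated correlation), and Saa3 was at -0.93 (adjusted p = 0.151). Respiratory chain genes stood at 0.09, ribosome biogenesis genes at 0.08 and MHC class II genes at -0.29 (camera adjusted p = 1.94e-07, 0.0085 and 0.00498, and adjusted p = 0.377, 0.562 and 0.562 with an estimated correlation). Other cell markers lay low in the same pool, at -0.32 for fibroblast, -0.13 for B and plasma cell, -0.18 for macrophage and -0.42 for smooth muscle genes (camera adjusted p = 0.0455, 0.0384, 0.0664 and 0.0986, and adjusted p = 0.729, 0.631, 0.729 and 0.753 with an estimated correlation). The fibroblast and B and plasma cell calls were lost without the control pools of days 4, 7 or 14 (adjusted p up to 0.173 and 0.144), with fibroblast genes at -0.19 without that of day 14.

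**Figure D2:**
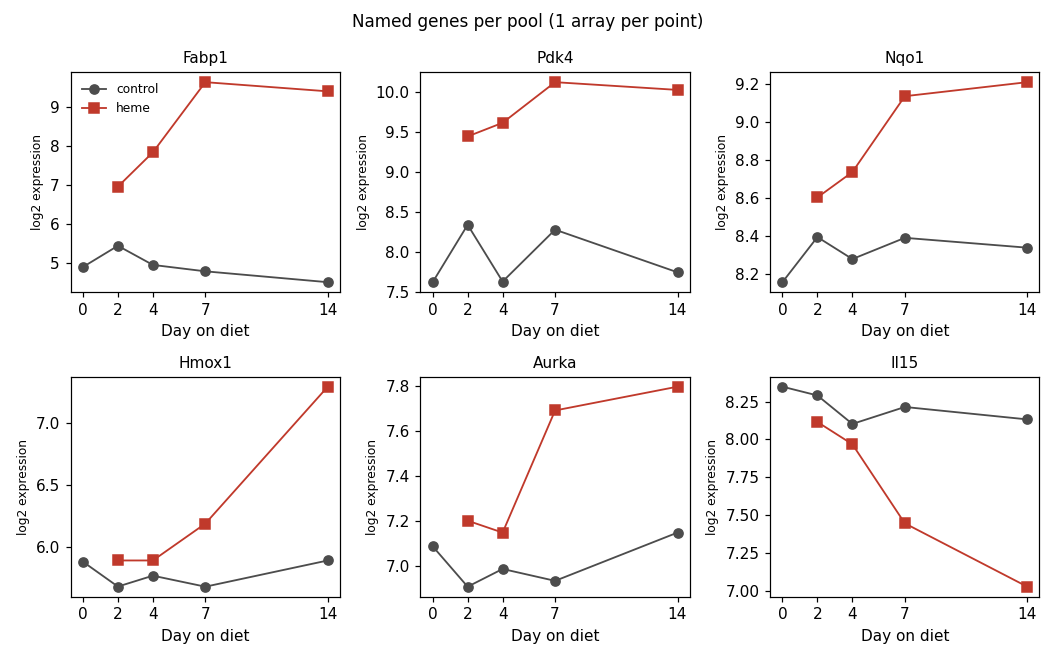
Log2 expression of Fabp1, Pdk4, Nqo1, Hmox1, Aurka and Il15 against the day on diet, with 1 point per pool (control in grey circles, heme in red squares). Fabp1 stands 2.05 log2 above the control mean in the heme pool of day 2, and Hmox1 stands 0.11 above it on days 2 and 4 and 1.52 above it on day 14.

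On day 4 camera with preset correlation had also called further lists. Heat shock and metallothionein (0.25), xenobiotic (0.16), other antioxidant (0.09) and colonocyte genes (0.06) were higher. Antimicrobial (-0.34), interferon (-0.14) and clock genes (-0.07) were lower. Of these, only the heat shock and interferon calls stayed when any pool was left out. The interferon mean was 0.002 against the same day's control pool. By day 7 genes were called in both directions. Fabp1 was 26.8-fold above the controls (log2 fold change 4.74, SE 0.30, adjusted p = 0.0079), Akr1b8 4.78-fold (adjusted p = 0.0084) and Acot2 1.72 log2 above them (adjusted p = 0.0041). Slc30a10, a manganese exporter, was 3.89-fold lower (log2 fold change -1.96, SE 0.11, adjusted p = 0.0057), Sis, the brush-border sucrase-isomaltase, 3.31-fold (adjusted p = 0.0311), Slc13a1, a sulfate transporter, 3.17-fold (adjusted p = 0.0057) and Slc46a1, the proton-coupled folate transporter, 2.35-fold (adjusted p = 0.0267). Cyp2f2 was 2.10-fold and Saa3 2.06-fold lower (adjusted p = 0.0133 and 0.0097). Of the fatty acid list 16 of 25 genes rose, and 24 adjusted over the list alone (mean 1.14, camera adjusted p = 4e-34, adjusted p = 0.259 with an estimated correlation). Among Nrf2 targets 10 of 26 rose, and 22 adjusted over the list alone (mean 0.54, camera adjusted p = 6.44e-23, adjusted p = 0.259 with an estimated correlation), including Nqo1 at 0.83 (adjusted p = 0.0233), whereas Hmox1 was at 0.41 (adjusted p = 0.116). Catalase rose by 0.91 (adjusted p = 0.0283). Mitosis genes rose in 7 of 25 cases, and in 25 adjusted over the list alone (mean 0.71, camera adjusted p = 1.75e-26, adjusted p = 0.315 with an estimated correlation). They included Hmmr, a spindle-associated hyaluronan receptor (0.84, adjusted p = 0.0227), the centromere protein Cenpf (0.66, adjusted p = 0.0329), Nusap1 (0.80, adjusted p = 0.0371) and Ube2c (0.74, adjusted p = 0.0349). Aurka rose by 0.68 (adjusted p = 0.0382) and Top2a by 0.65 (adjusted p = 0.0499), while Mki67 was at 0.71 (adjusted p = 0.0659).

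The same pool was lower in signals that restrain growth, in hormone-cell genes and in clock genes. Of the 4 growth inhibitors, 2 fell, both over all genes and adjusted over the list alone, the cytokine Il15 by 0.77 log2 (adjusted p = 0.0325) and Bmp2 by 0.66 (adjusted p = 0.0368) (list mean -0.47, camera adjusted p = 0.00215, adjusted p = 0.423 with an estimated correlation). Wif1 and Ihh were at -0.30 and -0.14 (adjusted p = 0.469 and 0.649). Chga fell by 0.98 (adjusted p = 0.0333) and Chgb by 0.60 (adjusted p = 0.0473), 2 of 16 enteroendocrine genes, with 5 lower adjusted over the list alone (list mean -0.26, camera adjusted p = 0.00927, adjusted p = 0.315 with an estimated correlation). The clock genes Per3 and Per2 fell by 0.64 and 0.38 (adjusted p = 0.0228 and 0.0383), 2 of 13, with 7 lower adjusted over the list alone (list mean -0.27, camera adjusted p = 2.98e-05, adjusted p = 0.315 with an estimated correlation). Genes of wound repair had a mean of 0.21 with 0 of 16 called over all genes and 1 adjusted over the list alone (camera adjusted p = 0.0197, adjusted p = 0.595 with an estimated correlation), Sprr1a being at 1.26 (adjusted p = 0.067). That call was lost without the control pool of day 2 (adjusted p = 0.0648), and the control pool of day 7 itself stood at 0.11. T and NK cell genes had a mean of -0.19 (0 of 9 called in either way, camera adjusted p = 0.027, adjusted p = 0.315 with an estimated correlation). Smooth muscle genes stood 0.60 log2 above the control mean in this pool and 1.16 above it in the control pool of the same day, the highest values of the 9 arrays. Camera with preset correlation also called DNA replication (0.18), cholesterol synthesis (0.25), respiratory chain (0.13), other antioxidant (0.16) and xenobiotic genes (0.20) higher on day 7. It called goblet (-0.16), tuft (-0.21) and crypt and stem cell genes (-0.10) lower. The control pool of day 7 itself stood at -0.15 for goblet genes.

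In total 244 genes were called on day 7, 132 higher and 112 lower, with 2510 at an unadjusted p under 0.05. This count fell to 68, 20, 22, 16 and 8 without the control pools of days 0, 2, 4, 7 and 14, and to 32 with the smooth muscle score as a covariate, a choice made after seeing the data. Fabp1, Acot2 and Slc30a10 were the 3 of 36 named called genes that stayed called in every leave-one-out fit (adjusted p up to 0.0495, 0.0486 and 0.0486).

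On day 14 the differences were the widest, with 4045 genes called, 1686 higher and 2359 lower, of which 89 were at least 2-fold apart (36 higher, 53 lower) and 6124 genes lay at an unadjusted p under 0.05. Fabp1 stood 22.7-fold above the controls (adjusted p = 0.0025), Clca4b, an epithelial protein of the calcium-activated chloride channel regulator family, 6.04-fold (adjusted p = 0.0161), Akr1b8 5.21-fold (adjusted p = 0.0025) and Pdk4 4.31-fold (adjusted p = 0.009). Slc13a1 was 4.80-fold lower (adjusted p = 0.0017), Sis 4.49-fold (adjusted p = 0.0045), Slc30a10 3.79-fold (adjusted p = 0.0023), Ang4, an antimicrobial ribonuclease, 3.57-fold (adjusted p = 0.0429), Tph1, which makes serotonin in enterochromaffin cells, 3.02-fold (adjusted p = 0.0048), and Mptx1, the mucosal pentraxin, 2.90-fold (adjusted p = 0.0041). Ang4 lost its call without the control pools of days 0, 2, 4 or 14 (adjusted p up to 0.0904). Hmox1 (probeset 10572897) rose 2.86-fold (log2 fold change 1.52, SE 0.10, adjusted p = 0.0025). It was 1 of 19 called genes among 26 Nrf2 targets, with 20 higher and 1 lower adjusted over the list alone (mean 0.70, camera adjusted p = 2.21e-12, adjusted p = 0.621 with an estimated correlation), as were Tkt of the pentose phosphate pathway (0.62, adjusted p = 0.0025) and Nqo1 (0.90, adjusted p = 0.0047). Fatty acid genes rose in 23 of 25 cases, and in 24 adjusted over the list alone (mean 1.06, camera adjusted p = 4.14e-14, adjusted p = 0.621 with an estimated correlation). Mitosis genes rose in 19 of 25 cases, and in 24 adjusted over the list alone (mean 0.56, camera adjusted p = 1.03e-09, adjusted p = 0.621 with an estimated correlation), among them Aurka (0.79, adjusted p = 0.0065), the cyclin Ccna2 (0.85, adjusted p = 0.0126) and the kinase Plk1 (0.79, adjusted p = 0.0131). Mki67 rose by 0.52 (adjusted p = 0.0369), a call lost without the control pools of days 2, 4 or 14 (adjusted p up to 0.0726).

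Further gene groups passed the test on day 14. As 4045 of all 14953 genes tested were called that day, counts of called members are to be read against that share. Every list that camera called on day 14 had also been called on day 7, with preset correlation on both days. DNA replication genes rose in 6 of 25 cases, also 6 adjusted over the list alone (mean 0.27, camera adjusted p = 1.93e-04, adjusted p = 0.621 with an estimated correlation), led by the cyclin Ccne1 (0.44, adjusted p = 0.0125) and the ribonucleotide reductase subunit Rrm1 (0.48, adjusted p = 0.0186). Cholesterol synthesis genes rose in 6 of 18 cases, and in 7 adjusted over the list alone (mean 0.44, camera adjusted p = 1.93e-04, adjusted p = 0.621 with an estimated correlation), among them Fdps (0.92) and Nsdhl (0.58), each with an adjusted p of 0.0169. The control pool of day 14 was itself above the control mean in both lists, by 0.16 for DNA replication and 0.17 for cholesterol synthesis, which left same-day differences of 0.10 and 0.27. Respiratory chain genes rose in 8 of 14 cases, also 8 adjusted over the list alone, by 0.14 on average (camera adjusted p = 1.93e-04, adjusted p = 0.621 with an estimated correlation). Goblet cell genes fell in 7 of 18 cases (mean -0.29, camera adjusted p = 0.00906, adjusted p = 0.638 with an estimated correlation). Adjusted over the list alone, 11 goblet genes were lower and 1 higher. Creb3l1 and the secreted Clca1 fell by 0.53 and 0.47 (adjusted p = 0.0077 and 0.0102), the secretory lineage factor Atoh1 by 0.51 (adjusted p = 0.017) and Muc2 by 0.23 (adjusted p = 0.018). Il15 fell by 1.19 (adjusted p = 0.0031) and Bmp2 by 0.77 (adjusted p = 0.006), 2 of the 4 growth inhibitors, with 3 lower adjusted over the list alone (mean -0.68, camera adjusted p = 0.0153, adjusted p = 0.621 with an estimated correlation). Wif1 and Ihh were at -0.55 and -0.23 (adjusted p = 0.0562 and 0.159). Colonocyte genes moved both ways, with 6 of 19 higher and 4 lower, and 6 and 5 adjusted over the list alone (mean 0.07, camera adjusted p = 0.757, adjusted p = 0.984 with an estimated correlation). Clock genes fell in 6 of 13 cases, and in 7 adjusted over the list alone (mean -0.26, camera adjusted p = 0.00849, adjusted p = 0.621 with an estimated correlation), Per3 by 0.59 (adjusted p = 0.006) and Nr1d1 by 0.42 (adjusted p = 0.0094). Chga fell by 1.36 and Chgb by 1.06 (adjusted p = 0.0041 and 0.0039), but the enteroendocrine list, with 5 lower and 1 higher of 16, missed the threshold (mean -0.48, camera adjusted p = 0.0657, adjusted p = 0.621 with an estimated correlation). The epidermal growth factor family member Ereg and the cytokine Il1b were at 0.21 (adjusted p = 0.417) and 0.39 (adjusted p = 0.0194).

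The heme array of day 14 itself stood apart. Its median correlation with the control pools over genes was 0.991, against 0.994 to 0.998 for the other arrays, and the median absolute deviation of its tested genes from the control mean was 0.229 log2, against 0.0707 to 0.103 on the others. Smooth muscle genes were -0.71 log2 from the control mean in it. Among the genes called, 512 were at least 1.5-fold apart. The number called lay between 2901 and 3619 when a control pool was left out, and it was 2601 without genes that have identical values in control pools, a choice made after seeing the data.

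The calls of days 7 and 14 overlapped. Of 132 higher genes on day 7, 124 were also higher on day 14, against 14.9 for independent lists of those sizes, and of 112 lower genes 103 were also lower, against 17.7. Both days were set against the same control pools. Simulated heme pools without any change, which is chance with no effect, shared 0 calls, and their top genes in lists of the observed sizes shared 45.2 higher and 46.8 lower genes. With different control pools for each day, 0 genes were called on day 7 in either direction, so no calls were shared, and top lists of these sizes shared 50 higher and 87 lower genes (both comparisons of top lists were chosen after seeing the data). Fold changes of both days correlated with r = 0.644 across genes, which are not independent replicates. The correlation was 0.173 in simulated pools and 0.450 with different control pools for each day. The covariance of 0.0345 stood above the 0.0034 that shared controls give, as computed from the control variances. Of the genes called between diets, 56 higher and 5 lower were also called on day 7.

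The difference between late and early days was then tested directly, setting the diet difference on days 7 and 14 against that on days 2 and 4. No gene was called in limma (990 at an unadjusted p under 0.05, smallest adjusted p 0.304). Fabp1 had a late-minus-early difference of 2.68 log2 and the clock output gene Dbp -0.59 (adjusted p = 0.304 each), Nqo1 0.48 (adjusted p = 0.394), Plk1 0.54 (adjusted p = 0.44), Bmp2 -0.57 (adjusted p = 0.454), Il15 -0.78 (adjusted p = 0.532) and Chga -0.94 (adjusted p = 0.424). Among the lists, Nrf2 targets differed by 0.35 (camera adjusted p = 6e-17), mitosis genes by 0.32 (adjusted p = 2.8e-14), fatty acid genes by 0.33 (adjusted p = 2.28e-08) and cholesterol synthesis genes by 0.27 (adjusted p = 3.78e-07), each larger on the late days. The clock list differed by -0.27 (adjusted p = 2.54e-06), growth inhibitors by -0.47 (adjusted p = 0.00165) and ribosome biogenesis genes by -0.17 (adjusted p = 0.00104). The cholesterol difference was 0.11 without the control pool of day 7, 0.42 without that of day 14 and 0.17 without the heme pool of day 14. These 7 lists stayed called in each leave-one-out fit, with adjusted p = 0.427 for the clock list and 0.511 for the others with an estimated correlation. Adjusted over the list alone, 6 Nrf2 targets, 2 fatty acid genes, 0 mitosis genes and 0 cholesterol genes were higher, and 6 clock genes, 2 growth inhibitors and 3 ribosome biogenesis genes were lower. When the heme pools alone were compared, days 7 and 14 against days 2 and 4, 183 genes were called, 60 higher and 123 lower, a contrast that does not take out what the control pools did over the same days.

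The control diet alone was checked for drift with the day. No gene had a slope past the threshold in limma (1073 at an unadjusted p under 0.05, smallest adjusted p 0.677). Of the lists, 18 were called with preset correlation. Stromal markers were higher at later days, with mean slopes per unit of log2(day + 1) of 0.28 for smooth muscle, 0.23 for fibroblast, 0.17 for endothelial and 0.12 for macrophage genes (camera adjusted p = 5.5e-04, 2.68e-07, 6.77e-09 and 3.97e-04, and adjusted p = 0.648 each with an estimated correlation). Adjusted over the list alone, 0, 4, 6 and 0 of their members rose. Other lists drifted too, with slopes of 0.07 for heat shock and metallothionein (camera adjusted p = 5.31e-04), 0.03 for DNA replication (0.00138), 0.04 for xenobiotic metabolism (0.00312), -0.03 for goblet (0.00323), 0.03 for fatty acid oxidation (0.00421), -0.06 for growth inhibitor (0.00501), 0.02 for Nrf2 target (0.00881), 0.10 for MHC class II (0.0115), 0.06 for B and plasma cell (0.0146), 0.10 for adipocyte, -0.01 for epithelial and 0.01 for respiratory chain genes (0.0179, 0.0339 and 0.0339). Immediate early genes had a slope of -0.04 (0.0339) and ribosome biogenesis genes 0.02 (0.0442). With an estimated correlation the adjusted p was 0.697 for these last lists and 0.648 for the others. Mitosis and clock genes had slopes of -0.01 and 0.02 (adjusted p = 0.211 and 0.339).

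**Figure D3:**
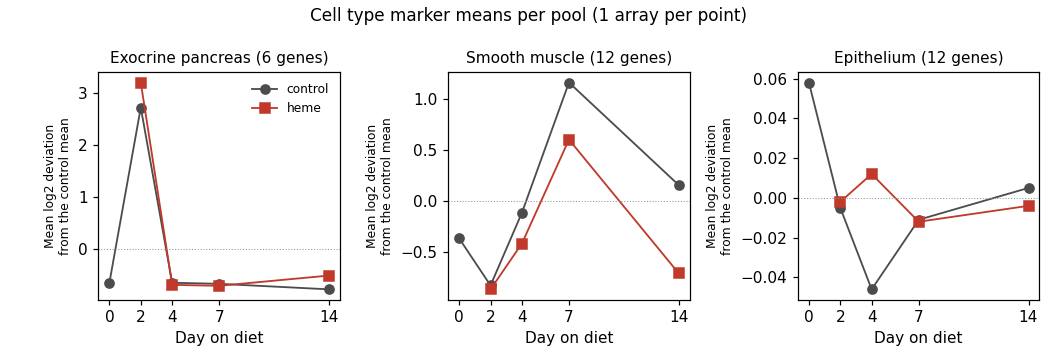
Mean log2 deviation from the mean of the 5 control pools for markers of exocrine pancreas, smooth muscle and epithelium, against the day on diet, with 1 point per pool (control in grey circles, heme in red squares). Pancreas genes stand at 2.71 and 3.19 in the pools of day 2, smooth muscle genes lie between -0.87 and 1.16, and epithelial genes between -0.05 and 0.06.

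Markers of smooth muscle and exocrine pancreas varied more between pools than those of the epithelium. Epithelial genes deviated from the control mean by -0.05 to 0.06 log2 over the 9 arrays, and their mean difference between diets was -0.0015 (camera adjusted p = 0.737). Smooth muscle genes ranged from -0.87 in the heme pool of day 2 to 1.16 in the control pool of day 7, with a difference of -0.35 between the diets (adjusted p = 0.189, and 1.95e-05 with the day as a block). Against the same day's control pool they were lower on all 4 days (-0.04, -0.30, -0.56 and -0.86). With the block, fibroblast, macrophage, endothelial and MHC class II genes were called lower too. On day 7 these lists were higher in the heme pool than in its control pool, by 0.06, 0.13, 0.04 and 0.11. Pancreas genes differed by 0.33 between the diets (adjusted p = 0.637), while the 7 arrays of other days lay between -0.77 and -0.50 log2.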

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

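The tests of a response to heme in the pancreas genes and of array brightness in the clock genes, and the further pancreas counts, were chosen after the results were seen. Of 182 groups of pools, 7 held a pool far from the others, and chance gives about 1 in 20.

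The list of exocrine pancreas genes set the pools of day 2 apart, in the control group (gap over range 0.963) and in the heme group (0.95). The 6 genes stood 2.71 and 3.19 log2 above the control mean there, and between -0.77 and -0.50 in the other 7 arrays. The carboxypeptidase Cpa1 was 23-fold and 36-fold above the other 7 arrays and the lipase Cel 15.4-fold and 25.1-fold (these names were chosen after their values were seen). A response to heme is argued against, since the control pool of day 2 stood 3.35 log2 above the highest other control pool. Pancreatic tissue carried into both pools may explain the pattern, but a further list of acinar cell genes left this open, with 59.1% (13 of 22) at least 2-fold up in both pools, between the bounds set for it. Of 19938 genes, 23 were at least 2-fold up in both pools and 19 of these were on the 2 lists, whose deviations in the 2 pools correlated with r = 0.983 across genes. The rest of the 23 were Reg1, Amy1, 2210010C04Rik and Gm5409, names chosen after their values were seen. The 9 members below 2-fold in 1 or both pools included bright genes (Spink1, Cela1, Nr5a2) and dim ones (Ctrc, Rbpjl, Ptf1a, Erp27 and Tmed6), names chosen after their values were seen.

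The diet difference of the clock genes was lower late than early, by -0.27. The heme pools stood at -0.10, -0.07, -0.27 and -0.26 from the control mean on days 2, 4, 7 and 14, and the control pools at -0.03, -0.05, 0.10 and 0.01. A difference in the time of killing that moves both arms of the clock is argued against: Arntl, Clock and Cry1, which peak opposite to Dbp, Per3 and Nr1d1, differed by 0.002 log2 from the same day's control on day 7 and by -0.08 on day 14. The other 3 genes fell by 0.58 and 0.59 on average. Clock itself was lower on day 14 (-0.271 to -0.254 from the control mean with a pool left out), so the mean of Arntl, Clock and Cry1 may hide movements of single genes. The brightness of the day 14 array is argued against as the whole cause on that day: after straightening the list stood -0.203 log2 from the control mean, against -0.261 before (control SD 0.0573), and 5 of 13 genes were called lower. A change of the clock by diet may remain. A difference in the time of killing that moves mainly a single arm is not covered by these means, and the hours of killing are not in the labels used here.

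Single pools stood apart in 5 further cases. Tuft cell genes were 0.13 log2 above the control mean in the control pool of day 2 (gap over range 0.848). Creb3l3 was at 6.17 log2 in the control pool of day 4, below the other control pools (0.731). Slc5a8 was at 11.27 in the control pool of day 7, below the others (0.853). Neuron and glia genes were 0.19 above the control mean in the heme pool of day 7 (0.878) and 0.31 above it in the control pool of that day. Slc26a3 was at 11.88 in the heme pool of day 14, below the other heme pools (0.857).

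The diet difference itself differed between late and early days in 13 lists by camera with preset correlation, and in 0 with an estimated correlation. Beside the clock list, 6 kept this in all 8 leave-one-out fits: Nrf2 targets (0.349), fatty acid oxidation (0.331), mitosis (0.318), cholesterol synthesis (0.267), ribosome biogenesis (-0.17) and growth inhibitors (-0.473). The other 6 lost it when some pools were left out. For enteroendocrine genes (-0.329, and -0.217 without the heme pool of day 14) these were the control pool of day 2 and the heme pool of day 7 (adjusted p up to 0.0649), and for lipogenesis (0.174) the control pool of day 7 and the heme pools of days 7 and 14 (up to 0.0973). Antimicrobial genes (0.236) lost it without the control pool of day 7 or the heme pools of days 4 and 7 (up to 0.47). Their value turned to -0.068 without the control pool of day 7, and was 0.539 without that of day 14 and 0.129 without the heme pool of day 14. DNA replication genes (0.068) lost it without the control pools of days 2 and 7 or the heme pools of days 4 and 14 (up to 0.965). Their value turned to -0.031 without the control pool of day 7, and was 0.166 without that of day 14, 0.112 without the heme pool of day 7 and 0.023 without that of day 14. Respiratory chain genes (0.048) lost it without the control pools of days 2 and 7 or the heme pools of days 2, 7 and 14 (up to 0.267), with a value of 0.017 without the heme pool of day 2 and 0.078 without that of day 4. Crypt and stem cell genes (-0.115) lost it without the control pools of days 4 and 7 or any of the 4 heme pools (up to 0.113).

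Among probesets without a gene name here, which the comparisons of genes do not use, 5 of 8322 differed between the diets, 3 higher and 2 lower in the heme pools (61 of 26667 probesets were called in that fit). Probeset 10393177 was 0.60 log2 higher and probeset 10339452 fell by 0.99 (adjusted p = 0.0189 for each, names chosen after the values were seen).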

How the results depend on the processing

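Cyclic loess, the smooth muscle covariate, the pools of day 2 or day 7 left out, genes with identical control values left out, the block for late minus early and the values of called genes and lists against the same day's control pool alone were chosen after seeing the data. With the control pool of day 7 left out, the late-minus-early values of 2 lists changed sign, antimicrobial defence (0.236, with -0.068 to 0.539 when a pool was left out) and DNA replication (0.068, with -0.031 to 0.166). Against the same day's control pool, the interferon list on day 4 turned from -0.142 (-0.179 to -0.098 with a pool left out) to 0.002. No other value of a called gene or list reversed. Of values of lists not called on a day, 25 changed sign against that pool, among them smooth muscle on day 7 (0.60 to -0.56). Under all alternatives, 9540 values of named genes stayed on their side of the threshold (without a test, within the control SD), 475 lost a call and 154 gained one. For lists 1011 values stayed and 164 lost their call. Against the same day's pool, without a test, 30 values of called genes and 21 of called lists moved by more than the control SD. The causes of the changes below were not tested, except where fewer arrays or genes explain them by construction.

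Between the diets, the 100 genes became 40 with a 1.5-fold minimum (37 higher, 3 lower), 49 over the 8 arrays of matched days, 30 to 251 with a pool left out and 0 in limma without both pools of day 7 (1567 at an unadjusted p under 0.05). The other settings gave 73 to 131. With an estimated correlation 0 lists were called between diets, on any day or late minus early, in camera.

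With the day as a replicate block, 77 genes (69 higher, 8 lower, 60 shared with the 100) and 22 lists, against 14, were called. Late minus early, the block gave 0 genes in limma (1162 at an unadjusted p under 0.05) and 17 lists, the 13 among them. It changed no call of a gene or list described other than those given beside the results.

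On day 2, the count of 0 genes became 16, all higher, without the control pool of that day (range 0 to 16 with a pool left out). That pool was the only control pool with high pancreas genes (2.71 log2 above the control mean, the others between -0.77 and -0.64). Whether the 16 genes are pancreas genes was not examined. At least 2-fold apart were 45 genes, and 14 against the same day's control pool alone.

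On day 4, the count of 1 gene became 11 with a further quantile normalization (8 higher, 3 lower), 9 with cyclic loess (7 higher, 2 lower) and 13 without genes of identical control values (10 higher, 3 lower). It was 0 in limma without the trend (1021 at an unadjusted p under 0.05), without a filter (1394), with the smooth muscle covariate (988), without the pools of day 2 (1224) or day 7 (936), and 0 to 1 with a pool left out.

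On day 7, the count of 244 became 115 without the trend, 93 without a filter, 404 with the 50th percentile filter, 472 with quantile normalization, 428 with cyclic loess, 428 without genes of identical control values, 32 with the smooth muscle covariate and 20 without the pools of day 2. With a pool left out it was 8 to 253.

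On day 14, the count of 4045 became 2601 without genes of identical control values and 2901 to 4055 with a pool left out, and 2899 to 4288 otherwise. The 9 lists became 18 with quantile normalization and 19 with cyclic loess.

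Late minus early, the count of 0 genes in limma became 183 in the heme pools alone (60 higher, 123 lower) and stayed 0 otherwise. The 13 lists became 22 in the heme pools alone, 8 without both pools of day 7, and 8 to 18 with a pool left out, with 8 without the control pool of day 7. The control slope called 0 genes under all settings. Signal over background limits the dimmest genes, and those with a mean under 4.716 log2 were not tested.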

Other observations

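The test of smooth muscle on day 14 and the splits within days were chosen after the results were seen, and the other tests of this part before.

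Of 16 genes of wound repair and epidermal growth factor signalling, 6 rose on day 14, also 6 adjusted over the list alone, and the list as a whole missed the threshold (mean 0.31 log2, camera adjusted p = 0.0657, adjusted p = 0.621 with an estimated correlation). Sprr1a, a cornified envelope protein induced by injury, rose by 1.88 (adjusted p = 0.0067), the urokinase receptor Plaur by 0.97 (adjusted p = 0.0161), the ephrin receptor Epha2 by 0.73 (adjusted p = 0.0134) and the interleukin 1 antagonist Il1rn by 0.44 (adjusted p = 0.0096). Of 18 genes of the crypt base, 1 rose and 5 fell, both over all genes and adjusted over the list alone, and the list was not called (mean -0.13, camera adjusted p = 0.0969, adjusted p = 0.621 with an estimated correlation). Over all 14953 genes tested, 1686 rose and 2359 fell on day 14, so such counts are not particular to the list. Lrig1 and Sox9 fell by 0.40 and 0.43 (adjusted p = 0.0058 and 0.012), and the Wnt inhibitor Rnf43 by 0.54 (adjusted p = 0.0163).

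Genes of heme and iron handling differed little in their mean between the diets. Of 17 genes 1 rose, with 2 higher and 2 lower adjusted over the list alone (mean 0.03, camera adjusted p = 0.363, adjusted p = 0.555 with an estimated correlation). Single members moved both ways on day 14, with 5 higher and 2 lower, also 5 and 2 adjusted over the list alone (mean 0.10, camera adjusted p = 0.185, adjusted p = 0.621 with an estimated correlation).

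The 4045 genes called on day 14 may reflect the heme diet or the state of that single array. A shift of the array that depends on brightness is argued against as the whole cause: after straightening, 2857 genes were called (1305 higher, 1552 lower), 2448 of them among the 4045. Random noise is argued against as the whole cause. On day 7, against other control pools, 86.2% of the genes lay on the same side, compared with 67.2% of all genes tested. Genes under the filter also spread more on the day 14 heme array. Their median absolute deviation was 0.158 log2, against 0.0864 to 0.110 on the other arrays, so some of the calls may be noise. Less smooth muscle in the scraping is argued against as the whole cause, with 2943 genes called when its score was a covariate. A difference of that pool in its animals or RNA has no replicate to test it and stays open.

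Of 100 splits of the 9 arrays that ignore the day, 1, the real one, gave as many genes called between the diets (100 genes, highest other 1). Chance was not excluded for the number of lists called by camera with preset correlation, where 24 of 100 splits gave as many (14 lists, highest other 21, median of the others 10, the highest in a split that set the control pool of day 14 and the heme pools of days 4, 7 and 14 against the rest). Splits that exchange the pools of whole days are too few for a share under 0.05. With the day as a block, 1 of 8 such splits, the real one, gave as many genes (77, highest other 0) and 1 of 8 as many lists (22, highest other 16). Without the block the real split gave 100 genes and the highest other 0.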
